A study of Mus musculus with 24 samples.

How the data were processed

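The data were peak lists from chromatin immunoprecipitation of H3K4me3, H3K27ac and H2A.Z in differentiated WT-1 brown adipocytes. Groups were taken from the sample labels: vehicle and stimulated wild-type cells (1 library per mark and condition), stimulated control and stimulated H2A.Z knockdown cells (2 libraries per mark and condition), and H2A.Z in stimulated cells (3 libraries). Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

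The H3K4me3 and H3K27ac lists were made with MACS 2.2.7.1 on 1 library each, per the file headers, with a q cutoff of 0.01, 1 tag kept per position and an effective genome size of 1.87e9. Wild-type libraries were called from single-end tags of 50 bases against the IgG library of the same condition and again against input, and control and knockdown libraries from paired-end fragments against 1 IgG library per condition, per the file headers. The knockdown and its IgG library therefore cannot be separated. Reads were placed on the mm10 build and deepTools 3.3.1 was used, per the submitters' processing notes, and the aligner was not given in the sources used here. The deposited lists give each peak's pileup signal, its fold enrichment over the local background as a ratio, and the −log10 of its q-value, all as the caller of the authors computed them within that list. The deposited H2A.Z lists give region width, height and total signal and a score, the height_logP, whose log base is not given in the sources used here, nor are the caller, background and depth. No H2A.Z score lay under 10.81, and region starts were multiples of 10. Because H2A.Z lists hold no q-value, the planned limit of 5 on −log10 q removed no H2A.Z region and was applied to the mark peaks only, and a height_logP of at least 20 was added as a stricter limit after the data were seen.

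Reads used by the caller, after duplicates were removed, ranged from 22453285 to 25697951 in the wild-type libraries and from 17305151 to 28971952 in the control and knockdown libraries. Scores, folds and pileups were used only within their own list; lists were compared by presence, overlap and covered bases. Covered bases are a proxy for signal: they do not follow the height of a region that stays called, and shallow libraries call shorter and fewer regions. Peaks on the 20 chromosomes 1 to 19 and X were used. Genes were 21631 protein-coding genes with coordinates on the same assembly. The gene table gave no strand, transcripts or exons, so the planned promoter window around a transcription start was replaced by 1 kb on each side of either annotated gene end (2.5 kb as an alternative), and exons, introns and UTRs were not assigned.

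Peaks of the lists compared were merged where they shared at least 1 base, and a region belonged to a list if a peak of that list overlapped it. Vehicle-only, stimulated-only and shared regions were counted in wild-type cells, with 95% exact (Clopper-Pearson) intervals that cover counting error only. In the knockdown comparison a lost region was called in both control and neither knockdown library, a gained region the reverse, and a kept region in all 4. The other 2 ways of splitting the 4 libraries into pairs stand beside these counts. Peak number and covered length were compared by an exact two-sided permutation test. Locus coverage was the number of bases under peaks in the gene body and 20 kb on each side. It was tested with limma 3.58.1 (empirical Bayes with a trend) in R 4.3.3 on log2(bases + 500), for loci with a mean of at least 500 bases, with Benjamini-Hochberg adjustment over loci and a threshold of 0.05, 1 fit per mark. A log2 ratio on this scale understates changes of sparsely covered loci, and neighbouring genes can share regions. SE is that of limma.

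The gene lists were fixed before the data were examined, as were the groups, tests, the rule for naming genes: thermogenic brown adipocyte genes, general adipocyte genes, acute cAMP and CREB targets, lipolysis and lipid droplet genes, fatty acid oxidation genes, respiratory chain and mitochondrial biogenesis genes, de novo lipogenesis genes, H2A.Z genes and their exchange machinery, loop and architecture genes, housekeeping genes, developmental transcription factors of other lineages, and markers of preadipocytes and fibroblasts, myocytes, macrophages and leukocytes, endothelial cells, neurons and hepatocytes. Lists were tested with camera from limma at a correlation of 0.01 between loci, with the estimated correlation beside it, and by Fisher's exact test of members with a changed region at a gene end, adjusted over lists. With 4 libraries the test with an estimated correlation has so few degrees of freedom that hardly any list could pass it. A failure there does not decide against a list call, and the preset correlation was not checked in another way. Wild-type lists were given as percentiles of their median among 10000 random lists matched on coverage in 20 bins (seed 13). H2A.Z regions called in all 3 libraries were set against the marks, with 100 shuffles within chromosomes (seed 11), and against region classes with Fisher's exact test and Mantel-Haenszel odds ratios over 5 strata of region length, all two-sided.

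For wild-type loci the ratio against input is given where its log2 value differs from that against IgG by more than 0.2 or has another sign, and for some others. The text names, per mark and comparison, up to 10 members each of the thermogenic, cAMP and lipolysis lists with a changed region at the locus, by size of the log2 ratio, the 5 largest rises and falls over all loci (past the threshold where tested, otherwise with at least 2 kb covered in 1 condition), and Ucp1, Ppargc1a, Dio2, Cidea, Pparg, Adipoq, H2az1, H2az2, Actb and Gapdh. Genes named outside this rule (Otop1 in H3K27ac, Gadd45b in the knockdown, Ehhadh, Acaa2, Acacb, Cox7b, Cpt1b, Ruvbl2, Ldb1, Fgb, Vegfa and Ppara in the knockdown H3K27ac, and members of the preadipocyte and fibroblast list) were chosen after their values were seen.

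Scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and Reactome terms of 15 to 200 tested loci from fgsea 1.28.0. The tests were checked on simulated data. For the locus fits, residuals were drawn independently for each locus and library, so the simulation held no library-wide shift and no correlation between loci. Its false calls therefore do not give the error rate of the fits to the real libraries. With 50 loci changed per size, the H3K27ac fit over 12872 loci recovered 34, 86, 100 and 100% of loci changed by a log2 of 0.5, 1, 2 and 3, with 7 false calls, and the H3K4me3 fit over 13598 loci 70, 96, 100 and 100%, with 4 false calls. The stratified odds ratio had a median of 0.50 at a true value of 0.5, and 92.0% of 200 intervals held it. Alternatives were the input library as background, a −log10 q of at least 5, the same number of peaks in each list, overlap of most of the region, merging within 1 kb, a pseudocount of 2000, no floor on covered bases, centring on library medians, 5 kb flanks, a replicate block, H2A.Z in at least 1 library and each replicate left out. Added after the data were seen were the stricter height_logP, leaving out regions with a peak of fold enrichment under 2, centring and left-out replicates for the gene lists, the Reactome terms, lost against gained regions and regions differing under the other splits as a reference for H2A.Z, and the wild-type ratios of loci called in the knockdown. Peaks on chromosomes M and Y were left out of all comparisons, and the 9 IgG and input samples had no list and entered only as the caller's background.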

Results

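Chromatin immunoprecipitation with sequencing, after digestion of crosslinked chromatin with micrococcal nuclease, an enzyme that cuts between nucleosomes, was carried out in WT-1 cells, a mouse brown preadipocyte line differentiated into adipocytes. The targets were H3K4me3, a histone mark of active promoters, H3K27ac, a mark of active promoters and enhancers, and H2A.Z, a variant of histone H2A encoded by H2az1 and H2az2. Cells for which the labels name no shRNA, called wild-type here, were given vehicle or CL316,243, an agonist of the β3-adrenergic receptor that switches on thermogenesis in brown fat, for 4 h, with 1 library per mark and condition. Cells transduced on day 6 with a non-targeting shRNA (control) or an shRNA against H2A.Z (knockdown) were given the agonist on day 11, with 2 libraries per mark and condition. H2A.Z was mapped in 3 libraries of stimulated cells without an shRNA. The 24 samples included 9 of IgG or input, and the other 15 had 19 peak lists.

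In the wild-type cells the H3K4me3 lists rested on 22453285 (vehicle) and 24034660 (stimulated) reads and the H3K27ac lists on 25697951 and 24562481 reads. In the control cells the H3K4me3 lists rested on 17305151 and 26103914 reads for replicates 1 and 2, and the H3K27ac lists on 28077457 and 24477579. The corresponding numbers in the knockdown cells were 24950405 and 28149546 for H3K4me3 and 26499261 and 28971952 for H3K27ac. The number of reads behind the H2A.Z lists was not given in the sources used here. A gene locus was taken as the gene body with 20 kb on each side, and its value was the number of its bases lying under called peaks.

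The knockdown aimed at the transcripts of H2az1 and H2az2, so both genes were examined first. H3K27ac covered 4272 ± 42.4 bases of the H2az1 locus in control and 4665.5 ± 361 in knockdown cells (SD, n = 2 each), a log2 ratio of 0.11 (SE 0.12, limma adjusted p = 0.72). At H2az2 the values were 7118 ± 28.3 and 6695.5 ± 165 bases, a log2 ratio of -0.08 (SE 0.11, limma adjusted p = 0.78). H3K4me3 at H2az1 and H2az2 had log2 ratios of 0.17 (limma adjusted p = 0.27) and 0.07 (limma adjusted p = 0.6), and each of the 4 libraries of each mark had peaks at both genes. An shRNA acts on the transcript, and histone marks at the target genes therefore check nothing about the knockdown. H2A.Z itself was not mapped in control or knockdown cells in the data used here, so its loss was not measured.

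The first comparison asked where the 2 marks differed between unstimulated and stimulated wild-type adipocytes. At Ucp1, which encodes the uncoupling protein that makes heat in brown fat (mm10 chromosome 8, 83290348 to 83298456), H3K27ac covered 7404 bases with vehicle and 10154 after stimulation (log2 ratio 0.43), and 5 regions at the locus were called after stimulation only against 0 with vehicle only. Against the input library in place of IgG the Ucp1 ratio was 0.09. Among the targets of cyclic AMP signalling, H3K27ac coverage was higher after stimulation at Sik1, a kinase gene induced by cyclic AMP (2213 and 4155 bases, log2 ratio 0.78, or 1.52 against input), and at Nr4a1, an immediate early nuclear receptor (10372 and 14118 bases, 0.43). It was lower at Il6 (-0.49, or -1.01 against input), Rgs2 (-0.39), Gadd45b (-0.32, or -1.23 against input), Vegfa (-0.30) and Gprc5b (-0.24). Klf9 (-0.29) and Jun (-0.28) were lower with IgG but at -0.04 each with input. Atf3 had 180 bases with vehicle and was listed at 0 after stimulation, with no peak in either list against input. In the thermogenic list, Gk (0.38) and Elovl6 (0.23) had higher values, while Adrb3, which encodes the receptor of the agonist, had 6028 bases with vehicle and 3392 after stimulation (-0.75), and Ebf2, a transcription factor of brown adipocytes, 25118 and 18378 (-0.44). Ppargc1a (-0.26), Ckmt1 (-0.17) and Cidea (-0.13) were lower and Dio2 had no peak in any of these lists. Prdm16 was at -0.24 (-0.00 against input). Ppargc1b was at -0.17 with IgG and 0.23 with input. Each condition had 1 library per mark, so none of these differences has a replicate check and no p-value was computed.

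Among lipolysis genes the largest H3K27ac difference was at Aqp7, the glycerol channel, with 7234 and 5009 bases (log2 ratio -0.49), followed by G0s2 (-0.23), an inhibitor of the lipase Pnpla2, and Pnpla2 itself was at -0.10. Mgll (-0.15), Abhd5 (-0.13), the neighbours Plin4 and Plin5 (-0.10 each) and Pdk4 (-0.08) were lower, Fitm1 was at -0.09 with IgG and 0.07 with input, and Lipa was higher (0.06). Against input Mgll, Abhd5 and Pnpla2 were at -0.05 each, G0s2 at -0.14 and Lipa at 0.01. At Pparg, the master regulator of adipocyte differentiation (mm10 chromosome 6, 115360879 to 115490404), 87717 bases were covered with vehicle and 66527 after stimulation (-0.40), with 41 vehicle-only regions and 1 stimulated-only region. Adipoq (-0.08), H2az1 (-0.27), H2az2 (-0.23) and Actb (-0.26) were lower and Gapdh was higher (0.09, or 0.32 against input). The loci with the most higher values after stimulation were Ntsr2, a neurotensin receptor (1001 and 4437 bases, 1.72, or 2.18 against input), Ptp4a3 (728 and 3099, 1.55) and Rbp4, the retinol carrier (3895 and 8905, 1.10, or 1.31 against input). The neighbours Aldh18a1 and Tctn3 shared the same regions (741 and 2147 bases, 1.09, or 1.43 against input). The loci with the most lower values were Fam110b (2587 bases with vehicle), Dnajc18 (2543), Spata24 (2379, neighbouring Dnajc18) and Srgap3 (2292), which were all listed at 0 after stimulation, and Cyp2s1 (5772 and 667 bases, -2.43, or -1.95 against input). Against input Fam110b (1423 bases with vehicle) and Srgap3 (506) were again listed at 0 after stimulation, while Dnajc18 and Spata24 had 2091 and 196 bases each (-1.90).

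Over all 12005 loci with H3K27ac the median log2 ratio was -0.21 (quartiles -0.42 and -0.05). Merging both H3K27ac lists gave 51381 regions, of which 31063 (60.5%) were called in both, 17814 in the vehicle list only (34.7%, 95% exact binomial interval 34.3 to 35.1) and 2504 in the stimulated list only (4.9%, 4.7 to 5.1). Shared regions lay within 1 kb of an annotated gene end more often (41.2%) than vehicle-only (17.7%) or stimulated-only (24.2%) regions. They were also longer (median 736 bases, against 238 and 242), and the shares were not adjusted for length. The lists held 52531 and 37840 peaks over 34.6 and 27.4 Mb. With the same number of peaks taken from each list, 7230 regions were vehicle-only and 5275 stimulated-only, and with peaks within 1 kb merged the numbers were 5777 and 586.

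Of the fixed lists, the preadipocyte and fibroblast markers stood furthest from matched loci in H3K27ac, with a median log2 ratio of -1.20 and all 9 covered loci lower after stimulation (percentile 0.0 of 10000 random lists matched on coverage). Examples, chosen after their values were seen, were Col1a1 (11989 and 4576 bases) and Col1a2 (14264 and 5948), which encode collagen I, Acta2, smooth muscle actin (4067 and 880), and Pdgfrb, a receptor of mural cells and fibroblasts (7741 and 3541, a log2 ratio of -1.03, or -0.53 against input). The general adipocyte genes (median -0.09, 4 higher and 18 lower, percentile 99.1), the lipolysis and lipid droplet genes (-0.09, 4 and 12, percentile 97.3), the respiratory chain and mitochondrial biogenesis genes (-0.06, 10 and 12, percentile 99.4) and the thermogenic genes (-0.10, 6 and 14, percentile 96.5) lay above matched loci although their medians were negative. Fatty acid oxidation (-0.11, percentile 92.0), de novo lipogenesis (-0.10, percentile 93.8) and H2A.Z machinery genes (-0.13, percentile 86.0) lay between these and the middle. Acute cAMP and CREB targets (-0.16, 8 higher and 18 lower, percentile 70.4), loop and architecture genes (-0.21, percentile 49.2) and housekeeping genes (-0.16, percentile 71.2) were closer to it. Markers of macrophages (-0.24, 4 loci, percentile 39.1), hepatocytes (-0.22, 4 loci, percentile 46.1) and myocytes (-0.11, 3 loci, percentile 70.5) had few covered loci, and endothelial markers, neuron markers and developmental transcription factors had 2 covered loci each, all lower, and were not ranked.

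In H3K4me3 the Ucp1 locus had 5658 covered bases with vehicle and 11450 after stimulation (log2 ratio 0.96, or 1.25 against input), with 7 stimulated-only regions and 0 vehicle-only. Only Il31ra, a cytokine receptor gene (675 and 2633 bases, 1.41), had a larger ratio among loci with at least 2 kb covered in 1 condition. Adcy3, an adenylyl cyclase (0.84), Acot3, a peroxisomal thioesterase (0.73), and Elmod2 (0.64), which neighbours Ucp1, followed. Nr4a1 (0.30), Sik1 (0.30), Irs2 (0.18) and the lipid droplet gene Hilpda (0.34, or 0.75 against input) were also higher, while Fosb (-0.20, or -0.10 against input), Abhd5 (-0.15), Gprc5b (-0.12) and Gadd45b (-0.11) were lower. Per1 was at -0.15 with IgG and -0.02 with input, and the sign turned with input at Pde4b (-0.18 and 0.01), Junb (-0.12 and 0.02), Rgs2 (-0.10 and 0.07), G0s2 (-0.04 and 0.06) and Aqp7 (-0.04 and 0.09), while Fitm1 was at -0.06 and 0.00. In the thermogenic list Acot11 (-0.78, or -0.09 against input), Esrrg (-0.38), Cox7a1 (-0.09) and Esrra (-0.09, or -0.04 against input) were lower, Otop1 was at -0.14 with IgG and 0.28 with input, and Ppargc1b (0.11, or 0.57 against input) and Pank1 (0.11, or 0.04 against input) were higher, as were the lipid droplet genes Plin5 (0.11), Plin2 (0.09), Mgll (0.09), Plin4 (0.08) and Plin3 (0.05). Ppargc1a (0.13, or 0.41 against input), Adrb3 (0.10), Cidea (0.06, or 0.43 against input), Adipoq (0.07), Gapdh (0.14) and H2az1 (0.01) were higher and H2az2 (-0.03) lower, and Pparg (-0.09 with IgG, 0.08 with input) and Actb (0.05 and -0.10) had opposite signs with the 2 background libraries. Dio2 had no H3K4me3 peak. The lowest ratios were at Hsd11b2, a steroid dehydrogenase (2570 and 660 bases, -1.40), Edar (-1.25), Gm52363 (-1.19), Cd93 (-1.14) and Gm29975 (-1.11). Against input Hsd11b2 was at -0.23, Edar at -0.52, Cd93 at -0.32 and Gm52363 at 0.08.

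The median over 14972 loci with H3K4me3 was -0.09. The lipolysis genes (median 0.04, 11 higher and 5 lower, percentile 100.0), general adipocyte genes (0.03, 15 and 7, percentile 100.0), respiratory chain genes (0.02, percentile 100.0), de novo lipogenesis genes (0.02, percentile 99.9), thermogenic genes (0.01, 13 and 9, percentile 99.9) and fatty acid oxidation genes (0.01, percentile 99.8) were above matched loci. So were H2A.Z machinery (-0.01, percentile 98.2), housekeeping (-0.02, percentile 98.1), hepatocyte (0.04, percentile 96.2) and, at percentile 95.8, cAMP target genes (-0.04). The preadipocyte and fibroblast markers (-0.18, 2 higher and 11 lower, percentile 4.5) were below them. Medians of the other lists were -0.10 for loop and architecture genes (percentile 24.3), -0.03 for macrophage (82.6), -0.10 for myocyte (58.0), -0.17 for endothelial (29.0) and -0.16 for neuron markers (22.0), and -0.12 for developmental transcription factors (38.8). Of 70592 merged H3K4me3 regions, 44532 (63.1%) were shared, 18584 (26.3%) vehicle-only and 7476 (10.6%) stimulated-only. Against input 11526 were vehicle-only, and with peaks within 1 kb merged 5806 were vehicle-only and 1651 stimulated-only.

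**Figure D1:**
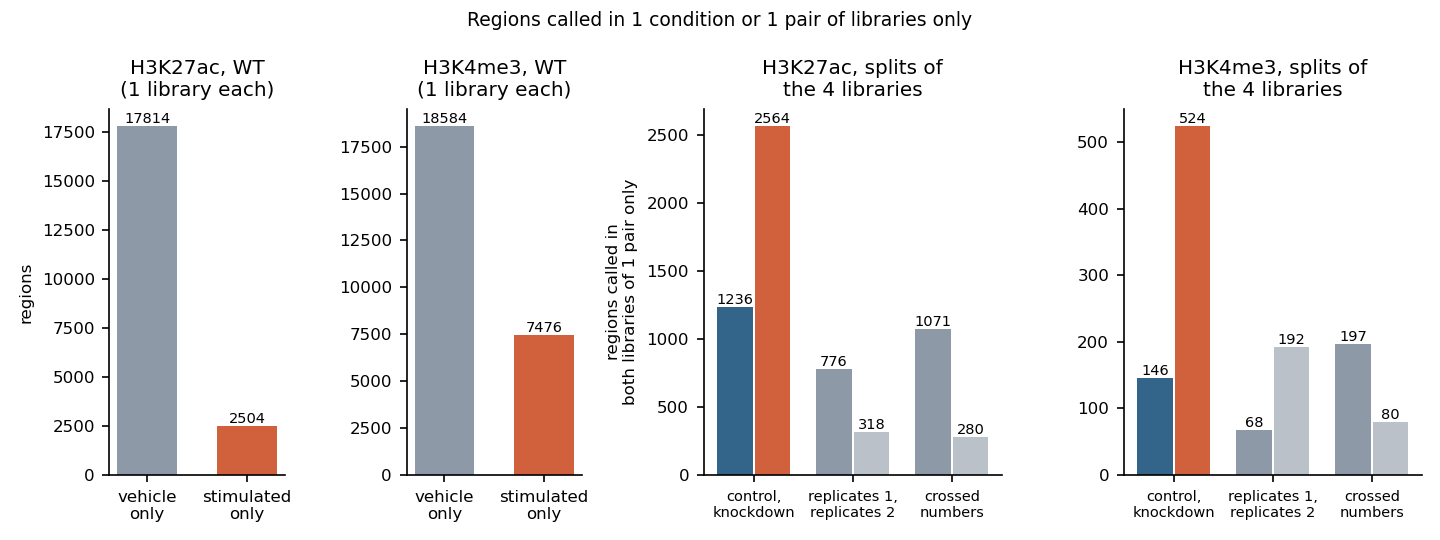
Bars give the number of regions called in 1 condition only: in wild-type cells (left pair of panels, 1 library per bar) and in both libraries of 1 pair but neither of the other (right pair, 4 libraries split in each possible way). For H3K27ac the control and knockdown split gave 1236 and 2564 regions and the other splits 776 and 318, and 1071 and 280.

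The second comparison asked how H3K27ac and H3K4me3 differed between knockdown and control cells, all stimulated. H3K27ac was called in both knockdown libraries and neither control library at 2564 of 48600 merged regions (5.3%), and the reverse, lost in the knockdown, held at 1236 (2.5%). For H3K4me3 524 of 19733 regions (2.7%) were gained and 146 (0.7%) lost. Other splits of the same 4 libraries into pairs gave 1094 and 1351 differing H3K27ac regions against 3800, and 260 and 277 differing H3K4me3 regions against 670. Lost and gained H3K27ac regions lay at gene ends less often (14.6% and 14.4%) than the 24323 kept regions (42.9%). The same held for H3K4me3 (20.5%, 30.7% and 74.3%). These shares were not adjusted for length, and longer regions touch a gene end more easily. Median lengths of lost, gained and kept regions were 425.5, 422 and 1432 bases in H3K27ac and 402.5, 374.5 and 2035 in H3K4me3. With the same number of peaks per list the excess of gains over losses was smaller, at 1724 and 1626 H3K27ac regions and 339 and 196 H3K4me3 regions. Merging peaks within 1 kb gave fewer lost and gained regions in both marks, and leaving out any 1 replicate gave more.

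H3K27ac lists held 38126 ± 3362 peaks in control and 42436 ± 1264 in knockdown cells (SD, n = 2 each), over 44.4 ± 4.2 and 44.9 ± 0.76 Mb. H3K4me3 lists held 17775 ± 460 and 18652 ± 176 peaks over 27.9 ± 0.17 and 30 ± 1.2 Mb. Log2 ratios of H3K27ac peak number and length were 0.15 and 0.01, with p = 0.33 and 1.00 in an exact two-sided permutation test (n = 2 against 2). Those of H3K4me3 were 0.07 and 0.10, each with p = 0.33 in the same exact test, and 0.33 is the smallest p that the design allows.

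At single loci, H3K27ac rose in the knockdown at 293 and fell at 66 of 12872 loci (limma, Benjamini-Hochberg adjusted p under 0.05). The largest rises were at Fam13c (mm10 chromosome 10, 70439972 to 70558736), with 115 ± 163 covered bases in control and 3300 ± 317 in knockdown cells (SD, n = 2 each), a log2 ratio of 2.65 (SE 0.22, limma adjusted p = 0.0017), at Mrc2, a collagen receptor (120.5 ± 170 and 2148.5 ± 189, limma adjusted p = 0.0037), and at Cdk18 (236 ± 65.1 and 2635 ± 655, limma adjusted p = 0.0022). Ston1 and Ankrd55 were listed at 0 in both control libraries and at 2440 ± 77.8 and 2191 ± 462 bases in the knockdown (limma adjusted p = 0.0017 and 0.0019). The largest falls were at Lhx3, a pituitary and motor neuron transcription factor (1091.5 ± 9.19 bases in control), and Zfp831 (1010.5 ± 336), both listed at 0 in the knockdown (limma adjusted p = 0.0089 and 0.015), and at Flrt1, Neurl1a and Amigo3, with log2 ratios of -1.39, -1.39 and -1.29 (limma adjusted p = 0.013, 0.035 and 0.017). Without the first control library the calls at Amigo3 and Neurl1a were lost (limma adjusted p = 0.079 and 0.13), and without the second so were those at Amigo3 and Flrt1 (0.062 and 0.081). When loci under the floor of 500 covered bases were tested too, 54 loci rose and 23 fell, Ston1 and Lhx3 still passed (limma adjusted p = 0.036 and 0.0092), and none of the other H3K27ac calls at genes named here did (Fam13c 0.19, Ppargc1b 0.53, Otop1 0.33, Pdgfrb 0.23, Acta2 0.16, Col1a2 0.38).

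Ucp1 had 24312 ± 3020 bases under H3K27ac in control and 19598 ± 206 in knockdown cells (SD, n = 2 each), a log2 ratio of -0.30 (SE 0.11) that did not pass (limma adjusted p = 0.19). It passed when each library was centred on its median (limma adjusted p = 0.0052) and without the second control library (0.032). Ppargc1b, a coactivator of mitochondrial genes (mm10 chromosome 18, 61291445 to 61400756), fell from 48072.5 ± 4740 to 32573 ± 778 bases (log2 ratio -0.55, SE 0.10, limma adjusted p = 0.017), and 4 regions at the locus were lost and 0 gained. Otop1, a proton channel gene of brown fat named as the other called member of its list (mm10 chromosome 5, 38277404 to 38304217), fell from 4834 ± 143 to 2897 ± 423 bases (log2 ratio -0.66, SE 0.13, limma adjusted p = 0.032). The Ppargc1b call was lost without either knockdown library (limma adjusted p = 0.42 and 0.34), and the Otop1 call without the first control, the second control or the second knockdown library (0.076, 0.073 and 0.27). Other thermogenic loci did not pass, with log2 ratios of -0.37 at Adrb3, -0.30 at Pank1, -0.24 at Elovl6, -0.21 at Prdm16, -0.19 at Cidea, -0.16 at Ppargc1a, -0.15 at Esrra, -0.13 at Ebf2 and -0.11 at Kcnk3 (limma adjusted p of 0.14 to 0.66). With each library centred on its median Adrb3 (limma adjusted p = 0.013), Ppargc1a (0.034), Prdm16 (0.037), Pank1 (0.043) and Ppara (0.016, named after its value was seen) also passed. These outcomes depend on the scaling. Dio2 was listed at 0 in every library.

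As a group, the 22 thermogenic loci tested were lower in H3K27ac in the knockdown than other loci, with a median log2 ratio of -0.16, 20 of 22 negative and 2 falling over all loci (2 when adjusted over the list alone). The camera adjusted p was 1.6e-04 with a preset correlation of 0.01, and the adjusted p = 0.83 with an estimated correlation. Fatty acid oxidation genes were also lower (median -0.19, 17 of 19 negative, 0 falling over all loci and 2 adjusted over the list alone, camera adjusted p = 2.8e-04), with the largest ratios at Ehhadh (-0.64) and Acaa2 (-0.41), enzymes of peroxisomal and mitochondrial oxidation that were named after their values were seen and passed over all loci only with centred libraries (limma adjusted p = 0.014 and 0.0054). For the fatty acid oxidation list the adjusted p = 0.83 with an estimated correlation. De novo lipogenesis genes (median -0.16, all 14 negative, 0 called over all loci and 0 adjusted over the list alone, camera adjusted p = 0.0043) and respiratory chain genes (-0.11, 19 of 22 negative, 0 and 0, camera adjusted p = 0.049) were lower as well, again with an adjusted p = 0.83 with an estimated correlation for both. The lipogenesis call was lost without either knockdown library, and the respiratory chain call without 3 of the 4 libraries. With centred libraries single members of both passed, such as Acacb (limma adjusted p = 0.004) and Cox7b (0.025), chosen after their values were seen.

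General adipocyte genes had a median H3K27ac log2 ratio of -0.06 (19 of 22 negative, camera adjusted p = 0.08) and lipolysis genes -0.08 (14 of 16 negative, camera adjusted p = 0.082). With each library centred on its median both passed (camera adjusted p = 0.007 and 0.019). Without centring the adjusted p = 0.87 with an estimated correlation for both. Pparg was at -0.06 and Adipoq at 0.03, and Mgll (-0.11), Lipe (-0.06), Plin5 (-0.03), Plin2 (-0.00) and Angptl4 (0.01), which build or break down stored lipid or control its uptake, did not pass. Of the 26 acute cAMP and CREB targets none passed over all loci (median 0.02, 15 positive and 11 negative, camera adjusted p = 0.63), and 1 rose and 1 fell when adjusted over the list alone. The widest were Il6, a cytokine gene, with 988 ± 952 bases in control and 3158 ± 253 in the knockdown (log2 ratio 1.46, SE 0.36, limma adjusted p = 0.065), and Pde3b, a phosphodiesterase that degrades cyclic AMP (-0.59, SE 0.14, limma adjusted p = 0.062). With centred libraries Il6 (limma adjusted p = 0.0067), Pde3b (0.001) and Vegfa (0.025, named after its value was seen) passed over all loci. Sik1 (0.32), Junb (0.17), Pde4b (0.13), Pde4d (-0.12), Per1 (0.09) and Egr1 (0.05) had limma adjusted p of 0.29 to 0.93.

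The preadipocyte and fibroblast markers rose as a group in H3K27ac, with a median log2 ratio of 1.16, 7 of 8 positive and 4 rising both over all loci and when adjusted over the list alone (camera adjusted p = 5.3e-06, adjusted p = 0.71 with an estimated correlation). The called members were Pdgfrb (823.5 ± 262 and 3846 ± 337 bases, SD, n = 2 each, log2 ratio 1.73, SE 0.17, limma adjusted p = 0.0022), Acta2 (1009.5 ± 50.2 and 3722.5 ± 408, 1.48, SE 0.15, 0.0022), Col1a2 (261 ± 369 and 2310 ± 75, 1.97, SE 0.30, 0.01) and Ly6a, which encodes the stem cell antigen Sca-1 (638 ± 584 and 2660 ± 433, 1.57, SE 0.30, 0.028). Without the second control library the Ly6a call was lost (limma adjusted p = 0.052). Fn1 (0.83), Col1a1 (0.63), Col3a1 (0.10) and Pi16 (-0.09) did not pass. A gained H3K27ac region lay at a gene end of 4 of 7 of these markers, where 405 of all 10463 genes with a region at an end had one (Fisher's exact test of the markers against the other genes, p adjusted over lists = 0.0012), the only such test to pass among the fixed lists. With the preset correlation, these markers of another cell state rose in H3K27ac while the thermogenic, fatty acid oxidation, lipogenesis and respiratory chain lists fell. None of these list calls held with an estimated correlation, a test with too few degrees of freedom here to decide. For the preadipocyte and fibroblast markers the unadjusted camera p went from 3.5e-07 to 0.047 although the estimated correlation was only 0.06. In the wild-type cells these markers were the lowest list after stimulation.

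**Figure D2:**
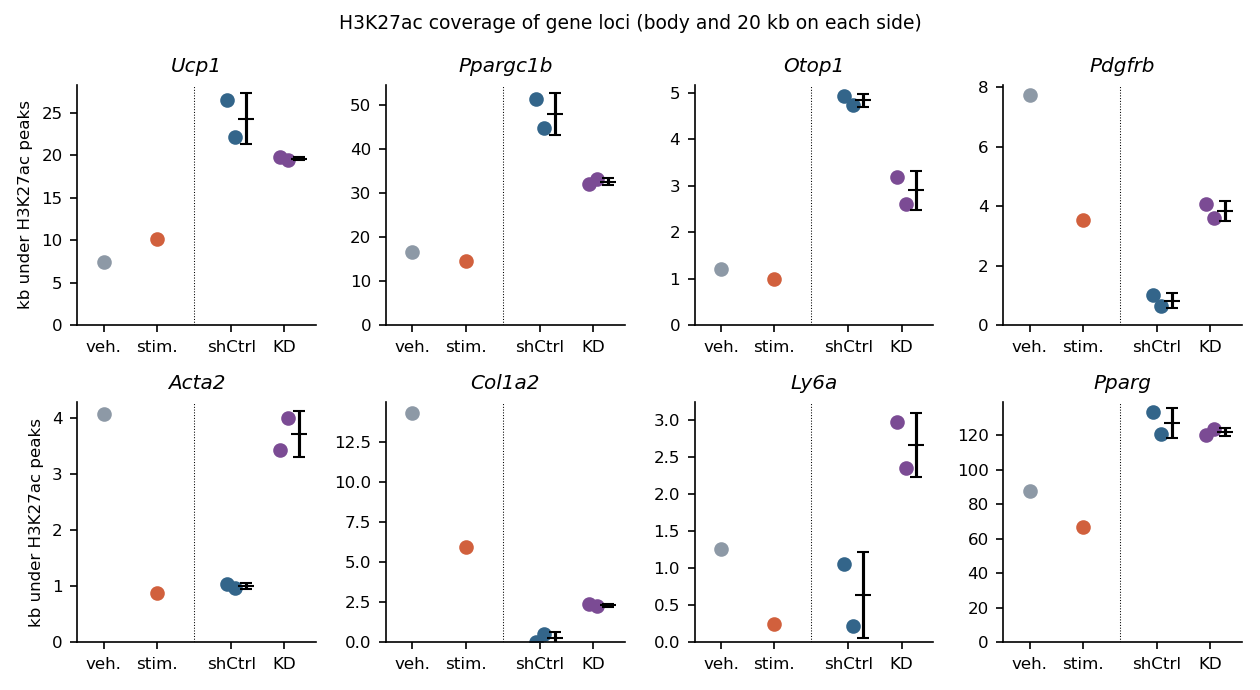
Points give kilobases under H3K27ac peaks at 8 gene loci in each library (wild-type vehicle and stimulated left of the dotted line, control and knockdown right of it), and bars the mean and SD of 2 libraries. Wild-type lists were called from single-end and the others from paired-end reads, so values compare only within a side; Pdgfrb lay between 638 and 1009 bases in control and between 3608 and 4084 in knockdown libraries.

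The remaining H3K27ac lists did not pass. Medians were -0.06 for H2A.Z machinery (9 of 16 negative, camera adjusted p = 0.97), -0.02 for loop and architecture genes (camera adjusted p = 0.75), -0.11 for housekeeping genes (0.3), -0.12 for myocyte (0.42), -0.01 for macrophage (0.75) and 0.09 for hepatocyte markers (0.63), and 0.14 for developmental transcription factors (0.14). None of their members was called over all loci or adjusted over the list alone, except 1 developmental transcription factor that rose in the latter. With centred libraries Ruvbl2 (limma adjusted p = 0.024), Ldb1 (0.048) and Fgb (0.039), chosen after their values were seen, passed. The test and the mean (0.03 each) were positive for loop genes and macrophage markers although the medians were negative. Endothelial (0.15) and neuron markers (-0.07) had 2 loci each and were not tested. Actb (0.04) and Gapdh (-0.04) did not pass. Centring each library on its median raised the calls over all loci to 735 rising and 586 falling and the share rising went from 81.6% to 55.6%, and without the second control library, where the control arm is 1 library and the spread comes from the knockdown pair alone, 150 rose and 151 fell.

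**Figure D3:**
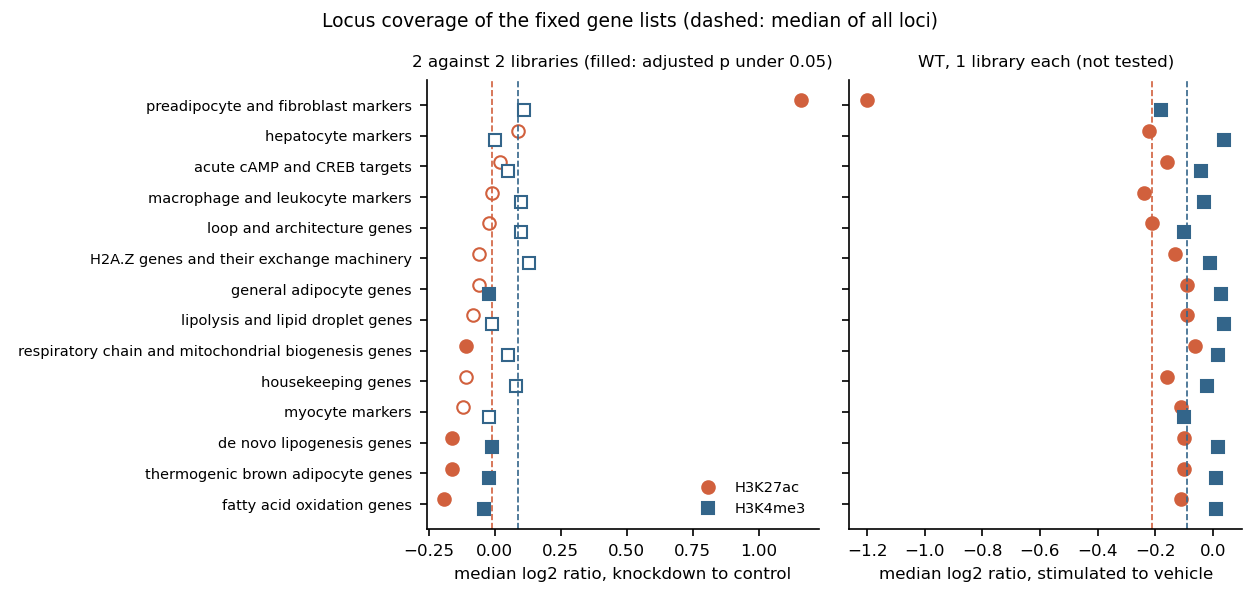
Points give the median log2 ratio of covered bases of each fixed list with at least 3 loci, knockdown to control (left, filled where the camera adjusted p was under 0.05 with a preset correlation) and stimulated to vehicle in wild-type cells (right, not tested), with dashed lines at the median of all loci. The preadipocyte and fibroblast markers stood at 1.16 on the left and -1.20 on the right in H3K27ac.

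In H3K4me3, 85 loci rose and 1 fell in the knockdown among 13598 (limma, adjusted p under 0.05). The largest rises were at neighbouring chemokine genes on mm10 chromosome 11 (82035577 to 82062955). Ccl2 and Ccl7, which attract monocytes and share the same regions, were listed at 0 in both control libraries and at 2330 ± 385 bases in the knockdown (SD, n = 2, limma adjusted p = 6.5e-04), and Ccl11, eotaxin, was listed at 0 and at 1450 ± 25.5 (limma adjusted p = 0.0058). Atp2b3 and its neighbour Bgn, which encodes the matrix proteoglycan biglycan, rose from 184 ± 260 to 1774 ± 287 bases (log2 ratio 1.78, SE 0.25, limma adjusted p = 0.028). The only fall was at Arhgef37 (mm10 chromosome 18, 61491657 to 61536928), from 5907.5 ± 202 to 4372 ± 133 bases (log2 ratio -0.40, SE 0.07), whose limma adjusted p lay just under the threshold and rounds to 0.05. With 5 kb in place of 20 kb on each side the Arhgef37 ratio was 0.10. Fewer loci rose and none fell with these smaller flanks, and the same held with a −log10 q of at least 5.

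The median H3K4me3 log2 ratio over all loci was 0.09, and 2398 loci were higher and 136 lower at an unadjusted p under 0.05. With each library centred on its median 90 rose and 47 fell, so that the share rising went from 98.8% to 65.7%. No locus passed without either knockdown library, and 7 and 17 rose without the first and the second control library. Without the floor on covered bases 39 rose and 4 fell, and of the genes named Ccl11 passed (limma adjusted p = 0.0077) while Ccl2 and Ccl7 (0.057), Bgn (0.35), Gadd45b (0.085) and Arhgef37 (0.27) did not. The other splits of the 4 libraries gave 0 calls in either mark. In those splits a difference between conditions adds to the spread within pairs and makes calls unlikely. Their count therefore gives no error rate for the calls, and the control and knockdown split also separates the IgG libraries.

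No thermogenic locus passed in H3K4me3 without centring. Ucp1 had 6633.5 ± 46 bases in control and 5828 ± 1150 in the knockdown (SD, n = 2 each, log2 ratio -0.18, SE 0.11, limma adjusted p = 0.38), and the ratio was 0.00 without the first knockdown library. Ppara, a fatty acid receptor (-0.21, limma adjusted p = 0.13), Ppargc1a (-0.17, 0.16), Pparg (-0.13, 0.22), Cidea (-0.10, 0.58) and Ebf2 (-0.04, 0.8) were at negative and Elovl6 (0.19, 0.31) and Kcnk3 (0.13, 0.48) at positive values. With each library centred on its median, where the median of all loci was 0.09 before, Ppara (limma adjusted p = 0.027), Ppargc1a (0.036) and Pparg (0.023) passed. Of the cAMP targets Gadd45b, a stress-induced gene named as the called member of its list, rose from 3997 ± 86.3 to 5787.5 ± 19.1 bases (log2 ratio 0.48, SE 0.07, limma adjusted p = 0.031). Nr4a1 (0.08), Pde4b (0.09), G0s2 (-0.06), Plin5 (-0.02), Adipoq (-0.02), Actb (-0.01) and Gapdh (0.07) did not pass.

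Relative to the other loci, 4 lists were lower in H3K4me3. They were the general adipocyte genes (median -0.02, 15 of 21 negative, camera adjusted p = 9.6e-06, adjusted p = 0.64 with an estimated correlation), the fatty acid oxidation genes (-0.04, 11 of 19 negative, 2.9e-05, adjusted p = 0.57 with an estimated correlation), the thermogenic genes (-0.02, 13 of 21 negative, 5.6e-05, adjusted p = 0.57 with an estimated correlation) and the de novo lipogenesis genes (-0.01, 8 of 14 negative, 6.1e-04, adjusted p = 0.62 with an estimated correlation). None of their members passed over all loci or when adjusted over the list alone, and the medians were near 0 where the median of all loci was 0.09. With centred libraries members of each passed, such as Pparg (limma adjusted p = 0.023), Cpt1b (0.044), Ppara (0.027) and Acacb (0.016), of which Cpt1b and Acacb were chosen after their values were seen. Lipolysis genes were at a median of -0.01 and a mean of 0.03 with a test towards lower values (camera adjusted p = 0.18, or 0.025 with centred libraries; adjusted p = 0.85 with an estimated correlation without centring). The cAMP targets (median 0.05, 20 of 28 positive, 1 rising over all loci and 4 adjusted over the list alone, camera adjusted p = 0.71), respiratory chain genes (0.05, 0 and 1, 0.3) and developmental transcription factors (0.05, 0.84) had positive medians and means and a test towards lower values. H2A.Z machinery genes were all positive (0.13, 16 of 16, 0 rising over all loci and 1 adjusted over the list alone, camera adjusted p = 0.62), as were the 9 preadipocyte and fibroblast markers (0.11, 0 and 2, 0.68). Loop and architecture genes (0.10, 0.68), housekeeping genes (0.08, 0.8), and macrophage (0.10, 0.71), neuron (0.21, 0.68), myocyte (-0.02, mean 0.13, 0.71) and hepatocyte markers (0.00, mean 0.06, 0.71) did not pass, the last pair with a test towards lower values, and the 1 endothelial locus was at 0.25. No list call in either mark held with an estimated correlation, but with 4 libraries that test could hardly be passed and decides little.

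The third comparison placed H2A.Z, mapped in stimulated cells, against both marks. At Ucp1 the 3 H2A.Z libraries covered 4460, 3840 and 3610 bases of the locus, and a region called in all 3 lay at a gene end of Ucp1, as it did at Ppargc1a, Cidea, Pparg, Adipoq, Sik1, Nr4a1, H2az1, H2az2, Actb and Gapdh. No such region lay at a gene end of Adrb3, Pnpla2, Plin5 or Dio2. The lists held 111188, 118234 and 126674 peaks over 43.4, 52.6 and 50.9 Mb, and pairs shared 0.552 to 0.586 of their joint length (Jaccard index). Of 187027 merged regions 44046 (23.6%) were called in all 3 libraries, 25324 (13.5%) in 2 and 117657 (62.9%) in 1. Of the regions called in all 3, 36.5% lay at gene ends, 22.5% in gene bodies and 41.0% between genes.

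In control cells 94.2% of the 15486 H3K4me3 regions called in both libraries overlapped H2A.Z called in all 3 libraries, against 4.5% after shuffling, and 64.6% of the 28680 H3K27ac regions did (4.1% shuffled). In stimulated wild-type cells the shares were 54.7% for H3K4me3 (3.3% shuffled) and 64.6% for H3K27ac (3.1% shuffled). H3K27ac regions at gene ends had H2A.Z at 93.3% in control and 92.1% in wild-type cells, and those elsewhere at 46.5% and 48.2%.

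Regions whose call differed in the knockdown had H2A.Z less often than kept regions. For H3K27ac 23.1% of lost and 39.7% of gained regions overlapped H2A.Z against 70.5% of kept regions, with odds ratios stratified by region length of 0.166 (95% interval 0.144 to 0.192) and 0.374 (0.339 to 0.412), and lost against gained regions gave 0.459 (0.393 to 0.535). Regions that differed under the other splits of the 4 libraries, where no condition differs, had H2A.Z at 30.0%, so that lost regions had it less often (stratified odds ratio 0.753, 0.641 to 0.883) and gained regions more often (1.58, 1.41 to 1.78) than these. For H3K4me3 54.8% of lost and 67.4% of gained regions had H2A.Z against 96.1% of kept regions (stratified odds ratios 0.127, 0.0892 to 0.18, and 0.21, 0.168 to 0.262) and 61.8% of those differing under the other splits. Against these last, the stratified odds ratio was 0.83 (0.567 to 1.21) for lost and 1.32 (1.02 to 1.7) for gained H3K4me3 regions. A lower share at lost regions was not shown in this mark. Lost against gained H3K4me3 regions gave 0.601 (0.413 to 0.874), which turned to 1.26 and 1.65 without the first and the second knockdown library. Regions are not replicates, and these intervals cover counting error only.

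**Figure D4:**
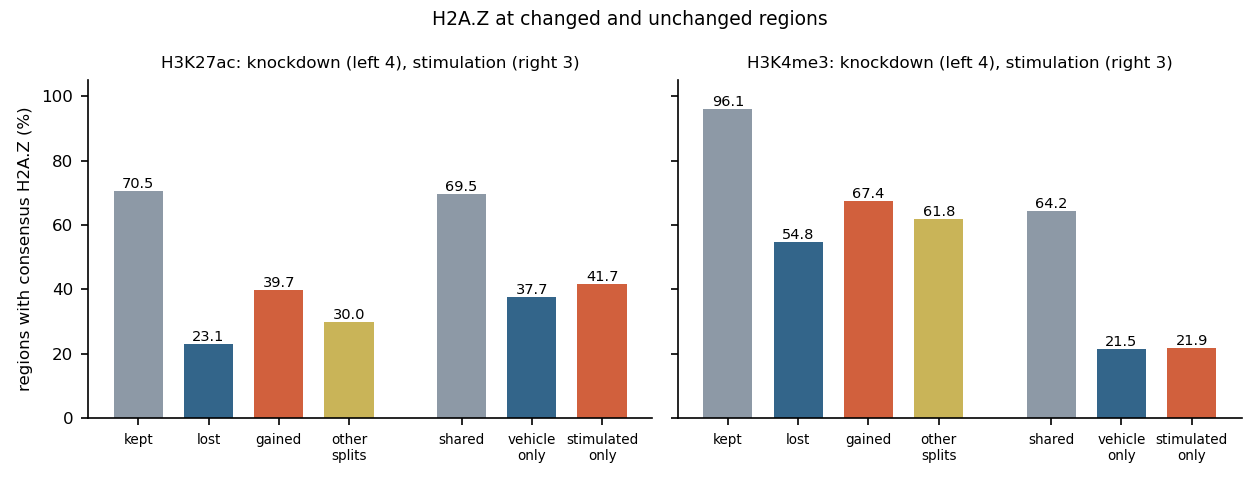
Bars give the percentage of regions that overlap H2A.Z called in all 3 libraries, for regions kept, lost or gained in the knockdown, regions that differ under the other splits of the same 4 libraries, and regions shared or called in 1 condition of the wild-type cells. Kept H3K27ac regions had H2A.Z at 70.5%, lost regions at 23.1%, gained regions at 39.7% and those of the other splits at 30.0%.

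In the wild-type comparison H2A.Z lay at 37.7% of vehicle-only and 41.7% of stimulated-only H3K27ac regions and at 69.5% of shared regions (stratified odds ratios 0.328, 0.311 to 0.347, and 0.393, 0.357 to 0.432). For H3K4me3 the shares were 21.5%, 21.9% and 64.2% (0.373, 0.353 to 0.395, and 0.401, 0.372 to 0.433). These tests compare single libraries, not the conditions. Vehicle-only and stimulated-only regions were also weaker calls than shared regions. For H3K27ac their median best −log10 q was 6.02 and 6.19, against 20 and 16.5 for shared regions. For H3K4me3 it was 5.28 and 5.31, against 21.5 and 18.5. The odds ratios were stratified by length and not by call strength, so the lower shares cannot be told apart from an effect of weak calls.

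Last, H3K27ac regions called only after stimulation in wild-type cells were followed into the knockdown. Of these, 25 lay at lost and 1949 at kept regions (1.27% lost), against 41 and 28892 (0.14%) of the regions shared with vehicle. The odds ratio was 9.04 (95% interval 5.49 to 14.9, Fisher's exact test p = 9.50e-14), or 3.05 (1.75 to 5.33) stratified by length. This p-value counts regions, which are not replicates, and measures no spread between cultures. Vehicle-only regions had 243 at lost and 9029 at kept regions (2.62%), a higher share than that of stimulated-only regions. The odds ratio of 9.04 is therefore not particular to regions called after stimulation. Each class lay at gained regions more often than at lost regions, with 61 stimulated-only, 493 shared and 923 vehicle-only regions there. Stimulated-only regions thus differed in both directions, and the odds ratio of 9.04 covers losses only. They were also weaker calls than shared regions (median of the best −log10 q 6.19 and 16.5). For H3K4me3 1 stimulated-only region lay at a lost and 144 at kept regions, against 100 and 16800 shared regions, an odds ratio of 1.17 (0.162 to 8.42, Fisher's exact test p = 5.79e-01), or 0.489 (0.067 to 3.57) stratified by length, so the direction was not settled. Without the first and the second control library the stratified H3K4me3 ratio was 1.87 and 1.38.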

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

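The tests on lower depth of 1 control library and on the different IgG libraries were chosen before the result was seen, and all other tests here were chosen after it was seen.

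Peaks lay on chromosomes that were left out of every comparison. The Y chromosome held 4 H3K4me3 peaks of the vehicle list against IgG, and 58, 60 and 57 regions of H2A.Z replicates 1, 2 and 3. The mitochondrial chromosome held 9 and 10 H3K27ac peaks of the vehicle and stimulated lists against input, and 22 and 21 regions of H2A.Z replicates 1 and 2. Their cause was not tested.

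The wild-type H3K4me3 lists held 55265 to 70085 peaks against either background and the control and knockdown lists 17450 to 18777. Deeper sequencing of the wild-type libraries is argued against, because 3 of the 4 control and knockdown libraries used more reads than both wild-type libraries. For calling as single-end tags, H3K27ac was examined, which covered 27.38 Mb in the stimulated wild-type list, against 44.4 Mb on average in the paired-end control lists. By number of peaks the stimulated wild-type H3K27ac list (37840) lay between the control lists (40503 and 35749). H3K27ac is another mark in other libraries, so these values cannot exclude an effect of the calling mode on H3K4me3. Acetylated sites recovered in the wild-type H3K4me3 immunoprecipitate could account for part of the excess of peaks. Of the 41805 stimulated wild-type regions without H3K4me3 in the control lists, 46.9% lay at H3K27ac of both control libraries, against 2.4% after shuffling. Weak H3K4me3 at enhancers would give the same, and the choice stays open.

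The stimulated wild-type library had fewer H3K27ac regions than the vehicle library. Lower depth of the stimulated library is argued against, because the ratio of peaks was 0.72 and that of reads 0.956. Complete removal of the mark at all vehicle-only regions is argued against for the stimulated control cells, as 43.9% of these regions were called in both control libraries (74.7% of stimulated-only regions). Those lists came from transduced cells and paired-end reads and covered 47.38 and 41.47 Mb, against 27.38 Mb in the stimulated wild-type list. A site weakened by stimulation could still be called there, so a partial loss is not excluded. Weaker enrichment in the stimulated wild-type library alone could lie behind its fewer regions. Vehicle-only regions were, however, called in both control libraries less often than stimulated-only regions, with a stratified odds ratio of 0.264 (0.24 to 0.292), and this was not decided. The vehicle list was called with a fragment length of 164 bases and the stimulated list with 196, and their lowest called pileups were 9.28 and 11.8. Whether this difference in calling contributes was not tested. A true loss of acetylation on stimulation stays open, as each condition had 1 library.

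The knockdown had more gained than lost loci and regions. The excess of gained regions was smaller with the same number of peaks per list. With each library centred on its median, 735 H3K27ac loci rose and 586 fell, and 90 H3K4me3 loci rose and 47 fell. The size of the excess thus depends on list size and scaling. Lower depth of 1 control library may contribute to the excess in H3K27ac, since 150 loci rose and 151 fell without that library and 616 and 28 without the other, but either count rests on 1 control library with the spread of the knockdown pair alone, and depth is not separated from other traits of that library. Different IgG libraries for control and knockdown could contribute, since of 27 H3K27ac regions that differed in both marks only 3.7% went in opposite ways and 25 were gained in both, as a shared background library or a shared effect would each give. More undifferentiated cells in the knockdown cultures could contribute too, as the preadipocyte and fibroblast markers rose in H3K27ac while the general adipocyte genes had a median log2 ratio of -0.06, and this was not decided. In H3K4me3, control replicate 1 used 17305151 reads and control replicate 2 26103914, against 24950405 and 28149546 in the knockdown. The median log2 locus coverage was 11.94 in both control libraries and 12.01 and 12.08 in the knockdown libraries. Depth was not tested as a cause of the excess in this mark. A direct effect of H2A.Z on the marks stays open and untested.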

How the results depend on the processing

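Alternatives were chosen before the data were examined, except the tests added after the result was seen: the H2A.Z height_logP of at least 20, leaving out regions with low fold enrichment, and centring or left-out replicates for gene lists. Over 67 results, 470 alternative values were computed: 273 kept all replicates, of which 192 gave the same result, and 197 left out 1 replicate, of which 126 did. A result counted as the same when a tested value kept its direction and its side of the threshold, a count stayed within 1.5 times, an untested log2 ratio kept its sign, or a percentage stayed within its interval. Wild-type H3K27ac vehicle-only and stimulated-only regions were 7230 and 5275 with the same number of peaks and 5777 and 586 merged within 1 kb. For H3K4me3 vehicle-only regions were 11526 against input, and 5806 with 1651 stimulated-only when merged. Merging gave 565 lost and 1411 gained H3K27ac regions in the knockdown and 86 and 303 for H3K4me3, and the same number of peaks 339 gained. Without 1 replicate, lost and gained H3K27ac regions ranged from 2001 to 6101 and 3274 to 7337, H3K4me3 from 245 to 764 and 850 to 2013, and the log2 ratio of H3K27ac covered length from -0.08 to 0.11. H2A.Z lay at 66.2, 76.5, 96.8 and 76.8% of wild-type H3K4me3, wild-type H3K27ac, control H3K4me3 and control H3K27ac regions when called in at least 1 library, at 60.1, 66.1, 95.7 and 68.8% with a −log10 q of at least 5, and at 47.7, 57.9, 91.7 and 57.6% with a height_logP of at least 20. The H3K4me3 odds ratio of lost against gained regions was 0.68 with H2A.Z in at least 1 library and 0.79 with a −log10 q of at least 5, and 0.313 to 1.65 without 1 replicate; that of stimulated-only regions was 0.204 to 1.87. Rising and falling H3K27ac loci were 54 and 23 without a floor, 735 and 586 with centring, 149 and 32 with a −log10 q of at least 5, 169 and 30 with 5 kb flanks, and 139 to 616 and 28 to 151 without 1 replicate. For H3K4me3 they were 39 and 4 without a floor, 47 falling with centring, 35 and 0 with a −log10 q of at least 5, 8 and 0 with 5 kb flanks, and 0 to 17 and 0 without 1 replicate. With estimated correlation 0 lists were higher and 0 lower in H3K27ac and 0 lower in H3K4me3, and 2 to 5 H3K27ac lists were lower without 1 replicate. The H3K4me3 log2 ratio was 0.10 at Arhgef37 with 5 kb flanks, and -0.37 to 0.00 at Ucp1 without 1 replicate. The planned −log10 q of at least 5 gave no value for H2A.Z, whose lists have no q-value. The cause was not tested.

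With replicate numbers as a block, 618 and 241 H3K27ac loci and 919 and 44 H3K4me3 loci rose and fell. The log2 ratios of peak number and length with the block were 0.16 and 0.02 for H3K27ac and 0.07 and 0.10 for H3K4me3. The deviations of replicates with the same number correlated at -0.04 in H3K27ac and 0.02 in H3K4me3 over loci. These values gave no sign of pairing by number. A correlation over loci leaves out a shift common to all loci, and the labels do not say whether libraries were paired, so pairing was not decided.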

Other observations

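The tests here were chosen after the result was seen. The test of weak regions was added after lost and gained regions had been compared with kept regions, though before its own value was seen.

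Among Reactome terms, H3K27ac was lower in the knockdown at genes of pyruvate metabolism and the citric acid cycle (39 loci, median log2 ratio -0.15, camera adjusted p = 7.5e-05) and of the citric acid cycle alone (18 loci, -0.28, 1.3e-04). It was higher at genes of elastic fibre formation (27 loci, 0.30, 5 rising, 4.6e-04), extracellular matrix organization (159 loci, 0.10, 12 rising, 0.0013) and chemokine receptor binding (25 loci, 0.21, 3 rising, 0.0047). The adjusted p was 1 for each of these terms with an estimated correlation, a test that hardly any term could pass with 4 libraries. In H3K4me3 only pyruvate metabolism and the citric acid cycle passed (camera adjusted p = 0.031, or 1 with an estimated correlation).

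The 293 loci with more H3K27ac in the knockdown had less of it after stimulation in wild-type cells. Of 262 with wild-type coverage, 255 were lower, and their median log2 ratio of stimulated to vehicle was -0.71, against -0.21 for random loci matched on coverage. The 66 loci with less H3K27ac in the knockdown did not rise after stimulation, though whether they fell less than matched loci depended on the setting. Of 53 with wild-type coverage, 37 were also lower after stimulation, with a median of -0.17 against -0.21 for random loci (percentile 79.7). With peaks called against input the median was -0.11 against -0.20 (percentile 96.5). For loci called lower without the first and the second control library the medians were -0.03 and -0.13, against -0.19 each. Without the first and the second knockdown library they were -0.21 and -0.28, against -0.25 and -0.26. A candidate explanation is that stimulation lowers acetylation at the 293 loci and that knockdown cells keep it. The loss of H2A.Z in knockdown cells was not measured. Fewer differentiated cells in both the vehicle and the knockdown cultures could give the same -0.71. H3K27ac in vehicle-treated knockdown cells, and a count of differentiated cells in each culture, would tell these explanations apart. The random loci were matched on covered bases, not on peak strength. The vehicle list held more H3K27ac peaks than the stimulated list (52531 and 37840), and the knockdown lists more than the control lists (42436 and 38126 on average). Whether such differences between lists contribute was not tested.

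Lost and gained H3K27ac regions had H2A.Z less often than kept regions. Weak regions near the calling threshold may carry less H2A.Z whatever the comparison, since lost and gained regions together did not have it less often than regions differing under the other splits (stratified odds ratio 1.26, 1.13 to 1.41). That holds for gained regions (1.58), while lost regions alone had it less often (0.753, 0.641 to 0.883), and whether weak calls account for the whole difference at lost regions stays open. H2A.Z mapped in control and knockdown cells would test whether its loss goes with a change of either mark at the same region.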
